A study of Mus musculus with 4 samples.

How the data were processed

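RNA sequencing libraries came from thymocytes of mice aged 6 to 8 weeks, sorted by flow cytometry, per the labels; each of the 4 groups (WT group 2, WT group 3, KO group 2, KO group 3) held 1 library. The cell type field of the labels gives both WT libraries as group 2 and both KO libraries as group 3, against the sample titles and the series design, which cross genotype with sorted group. The titles were used, and the order of the sorted groups was checked in each genotype with genes of immature and mature thymocytes.

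The authors deposited a table of counts per Ensembl gene for the 4 libraries and a table of RPKM for each. Reads were aligned with TopHat2 2.0.12 to mm10, per the submitters' processing notes; the counting program, its annotation, strand setting and read layout are not recorded, so reads of overlapping or antisense genes cannot be told apart. The deposited RPKM were checked against the deposited counts through the gene length that they together imply. Wherever a gene had counts, its value gave a whole gene length within 0.01 bp. That length was the same across libraries for 100% of genes counted in more than 1 library. Values of 0 matched between each RPKM table and its count column. The RPKM served for that check only. Of 35275 gene IDs, 34490 were matched to symbols and mm10 coordinates in GENCODE release M21; the 785 unmatched held between 0.119% and 0.128% of the counts of a library and were kept in the totals. Every entry of the table was an Ensembl gene, and 7465 genes had 0 counts throughout.

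Counts were scaled with edgeR 4.0.16 (TMM factors; R 4.3.3). A gene was measured at 2 CPM in at least 1 library. The fold of 1 library over another was the log2 ratio of TMM-scaled CPM plus 0.5, with an exact conditional binomial 95% interval (Clopper-Pearson) for the ratio of counts without the pseudocount. A gene counted as higher or lower at 2-fold or more with an interval excluding 1. Intervals cover counting error only. Where a library had 0 counts, the fold printed is a bound against a floor of 3 counts in that library, which leaves out the error of the higher count; the lower limit of the interval is given beside it. No p-value was drawn from 1 pair of libraries.

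The shared genotype effect and the shared sorted group effect were tested with edgeR's quasi-likelihood F test on the counts (genes measured as above, model of sorted group plus genotype, 1 residual degree of freedom, Benjamini-Hochberg adjustment, threshold 0.05). The common dispersion was 0.0288, a coefficient of variation of 0.170, and the spread of each gene was shrunk fully to the trend, so a gene that differs in 1 pair only can pass. Fitted log2 folds are given with standard errors. In counts simulated from the 12490 measured genes for the genotype effect, 111 of 200 genes changed 2-fold were called (55.5%) with 7 unchanged genes called, and 170 of 200 changed 4-fold (85.0%) with 9 unchanged called. These counts followed the fitted trend, with no sorted group effect, no difference of the genotype effect between sorted groups and no spread particular to a gene. Genes with few counts were not among those changed. The false calls in the real libraries can therefore be more. For the fold rule in group 2, simulated libraries without changes put 30 genes past 2-fold with counting error alone and 152 with the common dispersion added, and 200 of 200 genes raised 4-fold were found.

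The 31 gene lists, written for this comparison, were fixed before the data were examined. They cover neddylation, cullins, NRF2, p53, DNA replication, mitosis, BCL2 genes of each kind, TCR, NF-kB, Notch, Wnt, STAT, interferon, hypoxia, amino acid, chaperone and proteasome genes. They also cover immature, maturing, CD4, CD8, regulatory and innate-like T cell genes, markers of other cells, sex-linked genes and genes induced by handling. For each, the median log2 fold was placed among 10000 random lists of equal size matched on mean expression in 20 bins, a description of these libraries and not a test. Some genes belong to more than 1 list, and thymocytes express part of the lists for other cells. Ribosomal protein genes were added after the data were seen.

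Genes were named by a rule fixed before the data were examined, leaving out unnamed and predicted genes, receptor and immunoglobulin segments, small RNAs, pseudogenes and sex-linked genes. It took Uba3; the 12 higher and 12 lower genes with the largest smaller fold over both sorted groups, past 2-fold in both and with 10 CPM; the 6 highest and 6 lowest in each sorted group; the 10 highest and 10 lowest from group 2 to group 3; the 5 largest differences of the genotype fold each way; and up to 4 genes per list, with Cd69, Cd4, Cd8a, Bcl2, Bcl2l11, Cdkn1a, Ccr7 and Rag1 in any case. This gave 167 genes, of which the text prints a part; 1 gene that the rule took from the group 2 to group 3 step is not reported here.

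Alternatives fixed beforehand were DESeq2 size factors, plain library totals, no filter beyond 1 count, 10 CPM, edgeR's filterByExpr, a pseudocount of 2 CPM, a 3-fold rule, DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's older quasi-likelihood, a model without the other factor, and genes outside the handling, interferon and other cell lists. Robust shrinkage, leaving out each library, called genes with the same direction in both pairs, and lists without shared members were chosen after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.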

Results

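Transcripts of sorted mouse thymocytes were counted in 4 libraries, 1 for each combination of 2 genotypes and 2 sorted populations. Uba3 encodes the catalytic subunit of the enzyme that activates NEDD8, a ubiquitin-like protein that switches on cullin ubiquitin ligases. The genotypes were Uba3F/F, called WT here, and Uba3ΔT, in which the gene is deleted in T cells, called KO. Group 2 was sorted as TCRβint CD69hi and group 3 as TCRβhi CD69hi, consecutive steps of the selection of T cells. The tables held 10299863 counts for WT group 2, 8043077 for WT group 3, 8964120 for the library labelled KO in group 2 and 9689339 for the library labelled KO in group 3. Of 35275 genes listed, 12490 reached a CPM of 2 (CPM is the count scaled to library size) in at least 1 library and were measured. With 1 library per group, no difference between 2 libraries had a replicate check, and the 95% intervals of ratios cover counting error only.

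The targeted gene went against its label. Uba3 (ENSMUSG00000030061, chromosome 6, 97183670 to 97205647 in mm10) had 453 counts in WT group 2 and 647 in the library labelled KO, a ratio of 1.70 (interval 1.5 to 1.9). In group 3 it had 356 and 856 counts, a ratio of 2.06 (1.82 to 2.34). A count over the whole gene cannot separate deleted from kept exons, so it neither places the deletion nor excludes it, and every direction below is that of libraries labelled KO over WT. The 15 genes of the neddylation machinery, Uba3 among them, had median log2 folds of 0.00 in group 2 and 0.07 in group 3, and the 18 cullin and COP9 signalosome genes of -0.04 and 0.14. In the cullin and COP9 list Cops8 rose over both sorted groups by 0.49 (log2, SE 0.15), while Cul3 was near its WT level in group 2 (-0.05) and higher in group 3 (0.68).

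In group 2, the question was how the genotype label separates cells at the earlier step. Nqo1 had 3 counts in WT and 207 in the library labelled KO, a ratio of 82.0 (27.7 to 401). Gzmc had 0 and 102 counts, at least 40.4-fold higher against a floor of 3 counts in the WT library, or 32.3-fold at the lower limit of the interval, which adds the error of the higher count. Sdc1 was 10.6-fold higher (6.65 to 17.7), Mpp4 9.86-fold (6.60 to 15.3) and Ly6c1 7.26-fold (5.59 to 9.54). Slc45a3 stood at 0.0200 of its WT level (0.00409 to 0.0595, 178 and 3 counts), Ctse at 0.0775 (0.0689 to 0.0869, 4801 and 313 counts) and Hoxa7 at 0.204 (0.124 to 0.323). Aldh3b1, Dynlt1b and Cep83os were lower in group 2 as well, by log2 folds of -2.10, -1.98 and -1.91, but stood at 0.02, -0.31 and 0.32 in group 3. In total 806 genes were higher and 305 lower by at least 2-fold with an interval excluding 1, and among the 9101 genes with 10 CPM in a library 176 and 103 were.

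In group 3, the same comparison was made at the later step. Nqo1 was higher here too, with 5 and 234 counts and a ratio of 40.1 (16.9 to 125). Ngp, a neutrophil granule gene, had 6 and 204 counts, a ratio of 29.1 (13.1 to 80.3), and was at 2 counts in both group 2 libraries. Rrp1 was 12.4-fold higher (11.2 to 13.7, 426 and 6169 counts), Lad1 11.3-fold (6.58 to 21.1), and Rrp8 and Exosc5 had log2 folds of 2.91 and 2.67. Hoxa7 stood at 0.0297 of WT (0.00951 to 0.0710, 144 and 5 counts), Slc45a3 at 0.0531 (0.0224 to 0.108), Ctse at 0.118 (0.107 to 0.129), Atoh1 at 0.120 (0.0710 to 0.192) and Arl5c at 0.207 (0.188 to 0.229). Here 271 genes were higher and 699 lower by the same rule, the opposite balance to group 2, and with 10 CPM the numbers were 112 and 94.

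**Figure D1:**
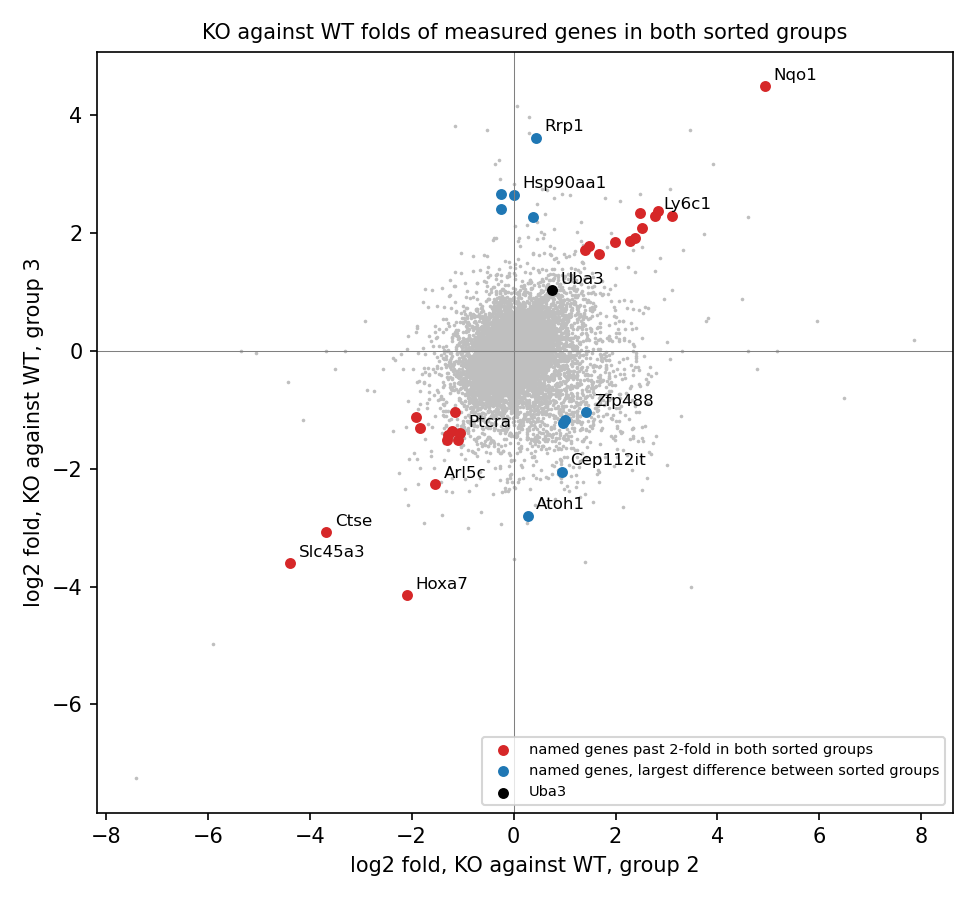
Log2 fold of libraries labelled KO over WT in group 2 (x axis) and group 3 (y axis); each grey point is 1 of 12490 measured genes, red points are named genes past 2-fold in both and blue points those with the largest difference between the sorted groups. Nqo1 lies at 4.93 and 4.49 and Slc45a3 at -4.38 and -3.61, while Rrp1 lies at 0.45 and 3.62.

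The genotype effect shared by both sorted groups was tested with edgeR's quasi-likelihood model of sorted group plus genotype. Its error term is the part of the effect that differs between the sorted groups, not variation between mice. That error was pooled over genes along the trend, so a small p does not show that a gene's own folds agree between the sorted groups. Nqo1 rose by 5.76 (log2, SE 0.52; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 2.85e-25). Ctse fell by 3.37 (SE 0.16; edgeR, adjusted p 6.51e-92), Slc45a3 fell by 4.74 (SE 0.55) and Arl5c fell by 1.89 (SE 0.15). Dusp5 rose by 1.39 (SE 0.14; edgeR, adjusted p 2.95e-20), from 237 and 263 CPM in WT groups 2 and 3 to 621 and 694 CPM. Uba3 rose by 0.90 (SE 0.17; edgeR, adjusted p 2.17e-05). In all, 367 genes rose and 226 fell at an adjusted p of 0.05; the numbers were 179 and 84 with edgeR's own filter, 0 and 1 with no filter, 28 and 11 without sorted group in the model, and 25 to 80 and 11 to 42 with 1 library left out. Of these 593, 551 had the same direction with an interval excluding 1 in both sorted groups, 334 higher and 217 lower. The other 42 include Hsp90aa1, with log2 folds of 0.00 in group 2 and 2.65 in group 3. Rrp1 counts among the 551, though its folds were 0.45 and 3.62, and both genes lost the call with DESeq2 and with robust shrinkage. DESeq2 with the same model called 125 higher and 54 lower, all 179 of them among the 593. Of the 86 named genes that edgeR called for genotype, 35 missed 0.05 with DESeq2 and 6 with limma-voom.

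Among genes past 2-fold in both sorted groups, with 10 CPM in at least 1 library of each pair and predicted or unnamed genes left out, those with the largest smaller fold were, after Nqo1, the genes Pcsk1 (log2 folds 2.83 in group 2 and 2.38 in group 3), Ramp3 (2.48 and 2.34), Ly6c1 (2.77 and 2.29), Sdc1 (3.10 and 2.28), Oas1a (2.52 and 2.09), Foxb1 (2.38 and 1.92), Dtx1 (2.29 and 1.86) and Plaur (1.99 and 1.85). Lad1 (3.91 and 3.17) and Mpp4 (3.07 and 2.75) were under 10 CPM in 1 of the pairs. With a pseudocount of 2 CPM these folds shrank to 2.44 and 2.53 for Lad1 and to 2.58 and 1.64 for Mpp4. Ly6a (1.67 and 1.65), Hey1 (1.47 and 1.78) and Klf11 (1.41 and 1.70) completed the higher side. On the lower side, after Slc45a3 and Ctse, came Hoxa7 (-2.09 and -4.15), Arl5c (-1.54 and -2.26), Klk1b22 (-1.83 and -1.31), Itgae (-1.30 and -1.51), Tmem242 (-1.28 and -1.43) and Nrp1 (-1.22 and -1.37). Hist1h2bg (-1.91 and -1.12), Afdn (-1.1 and -1.52), Ptcra (-1.05 and -1.40) and Fmnl2 (-1.15 and -1.05) were the last 4. All of these passed the edgeR test, and Hey1, Itgae, Afdn and Fmnl2 missed 0.05 with DESeq2. Members of the Ly6, Klk1b and histone families share sequence, so their counts are less certain. Ctse, Slc45a3, Arl5c, Oas1a, Dtx1, Ly6c1, Ly6a, Sdc1, Plaur, Klf11, Hist1h2bg, Ptcra, Lad1 and Mpp4 each lie within 1 Mb of another shared gene. Segments of another strain background may therefore contribute to their folds, as described below.

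**Figure D2:**
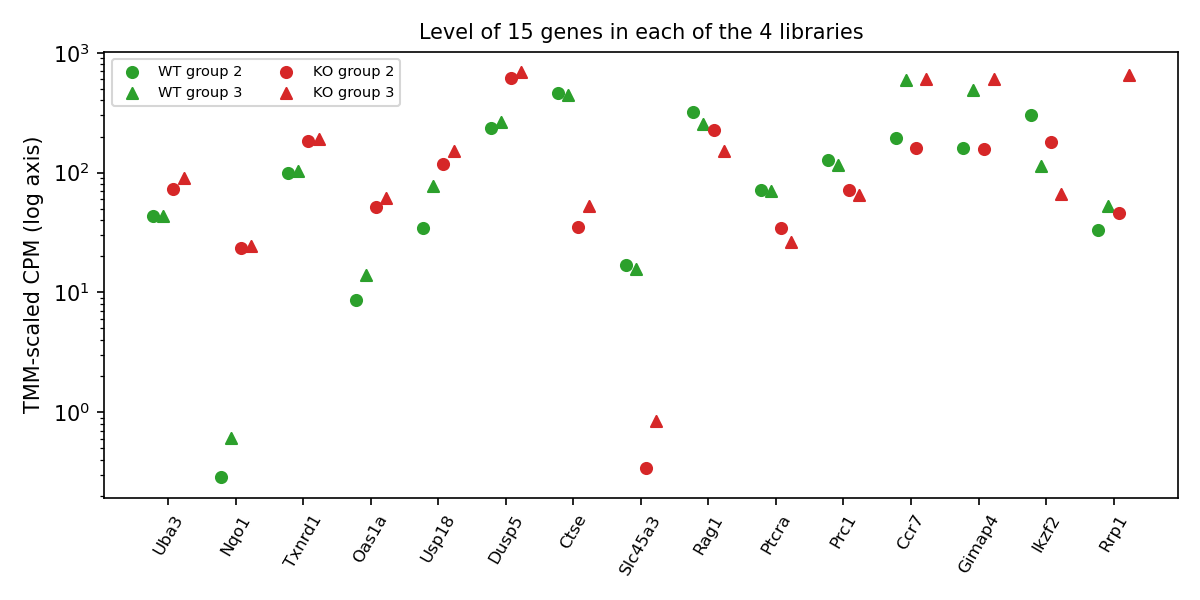
TMM-scaled CPM (log axis) of 15 genes in each of the 4 libraries; circles are group 2, triangles group 3, green WT and red labelled KO. Uba3 stands at 43.2 and 43.7 CPM in WT and at 73.3 and 89.9 CPM in the libraries labelled KO, and Ctse falls from 457 and 445 CPM to 35.5 and 52.3 CPM.

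By list median, antioxidant genes were higher and cell division genes lower in the libraries labelled KO, though not every member was called. Of the list genes given here as called by edgeR, Cops8, Ttk, Bub1, E2f8, Pola1, Slfn1, Elovl6, Slc6a19, Tnfrsf9, Nr4a2, Trib3, Sesn2, Jun, Cd74, Bbc3, Dnajb9, Hspa5, Socs3 and C1qb missed 0.05 with DESeq2. Targets of NRF2, a transcription factor degraded through a cullin ligase, had medians of 0.43 in group 2 and 0.44 in group 3, above all 10000 random lists matched on expression in each. Beside Nqo1, Txnrd1 rose by 0.89 (SE 0.15) and Gsr by 0.73 (SE 0.15), and Gsta4 was higher by 1.23 in group 2 and 0.23 in group 3; 10 of 23 rose over all genes and 11 adjusted over the list alone. Mitosis genes had medians of -0.66 and -0.57, below all random lists, and 22 of 25 fell (24 adjusted over the list alone), among them Ttk (-1.17, SE 0.24), Prc1 (-0.83, SE 0.16), Bub1 (-0.81, SE 0.22) and Cenpf (-0.80, SE 0.16). DNA replication and E2F target genes had medians of -0.26 and -0.33; E2f2 (-0.99, SE 0.17), E2f8 (-0.85, SE 0.27) and Pola1 (-0.70, SE 0.21) fell, and Ccne2 was lower without passing. On that list 5 fell and 1 rose over all genes, and 9 fell and 1 rose adjusted over the list alone.

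Interferon-stimulated genes had the highest list medians, 0.93 in group 2 and 0.64 in group 3. Oas1a rose by 2.34 (SE 0.22), Rsad2 by 1.45 (SE 0.26), Usp18 by 1.35 (SE 0.16) and Rtp4 by 1.30 (SE 0.16); 13 of 26 rose over all genes and 16 adjusted over the list alone. Maturation and egress genes had medians of 0.32 and 0.33, and 8 of 26 rose (13 adjusted over the list alone, with 2 lower), among them Ly6c1 (2.64, SE 0.26), H2-Q7 (0.79, SE 0.15), Slfn1 (0.65, SE 0.16) and Ms4a6b (0.58, SE 0.14). Genes of immature double-positive cells had medians of -0.23 and -0.37: Ptcra (-1.23, SE 0.18), Rag2 (-0.78, SE 0.15), Slc6a19 (-0.77, SE 0.19) and Rag1 (-0.62, SE 0.14) fell, and Elovl6 rose (1.17, SE 0.29). On that list 6 of 19 fell and 1 rose over all genes, and 8 fell and 1 rose adjusted over the list alone. Regulatory T cell genes had medians of -0.39 and -0.76, with Tnfrsf4 (-1.16, SE 0.20), Nrp1 (-1.31, SE 0.20), Ikzf2 (-0.76, SE 0.15) and Tnfrsf9 (-0.73, SE 0.18) lower and Capg (1.0, SE 0.18) and Izumo1r (0.84, SE 0.16) higher. Over all genes and adjusted over the list alone, 4 of its 13 fell and 2 rose. Oas1a, Ly6c1 and Ptcra lie near other shared genes, as above, so strain segments may contribute to their folds.

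TCR-induced, amino acid response, immediate early and B cell genes had medians above 0 in both sorted groups. TCR-induced genes had medians of 0.23 and 0.15; 7 of 28 rose and 1 fell, both over all genes and adjusted over the list alone, with Tox2 (1.29, SE 0.21), Nr4a1 (0.95, SE 0.14) and Nr4a2 (0.84, SE 0.25) next to Dusp5. Amino acid response genes had medians of 0.37 and 0.28, and Trib3 (1.94, SE 0.46), Cebpb (1.44, SE 0.23), Sesn2 (1.02, SE 0.32) and Slc3a2 (0.70, SE 0.14), 4 of 17, rose in both counts. Immediate early and heat shock genes, which tissue handling also induces, had medians of 0.33 and 0.31: Junb rose by 1.08 (SE 0.14), Ier2 by 0.77 (SE 0.14) and Jun by 0.56 (SE 0.14), and 6 of 16 rose over all genes (9 adjusted over the list alone), Hsp90aa1 among them although it differed in group 3 only. B cell markers had medians of 0.68 and 0.35, with Cd74 alone called (0.50, SE 0.15) and Cd79a at 0.96 and 0.47. Over genes with 10 CPM the group 3 median of the B cell list was 0.01, and Ighm, its most abundant gene at 6872 to 10996 counts per library, stood at -0.03 and -0.37.

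These 11 lists of 31 lay outside the central 95% of random lists in both sorted groups, 7 above and 4 below. TCR-induced genes in group 3 came within it with DESeq2 size factors (percentile 97.45, from 97.55) and without shared members (96.7), regulatory T cell genes in group 2 with a pseudocount of 2 CPM (2.6), and B cell markers in group 3 with that pseudocount (95.5). Others did so in 1 sorted group. In group 2 these were hypoxia and glycolysis genes (median 0.20, and 0.12 in group 3; Egln3 rose by 1.0, SE 0.17, and Aldoa by 0.52, SE 0.14), Notch targets (0.43 and -0.20; Dtx1 and Hey1 higher, Ptcra lower), erythroid markers (0.58 and 0.00; Hba-a1 at 0.64 and 0.21) and sex-linked genes (-0.57 and -0.03). In group 3 they were p53 targets (-0.07 in group 2 and 0.23 in group 3, the latter within the central 95% at 10 CPM, percentile 93.8, and without shared members, 97.2; Bbc3 rose by 0.78, SE 0.18), pro-death BCL2 genes (0.07 and 0.27, and -0.01 in group 3 without members shared with other lists; Bcl2l11 at 0.42 and 0.33, not called), endoplasmic reticulum chaperones (0.05 and 0.19; Dnajb9 rose by 0.85, SE 0.20, and Hspa5 by 0.43, SE 0.14) and myeloid markers (0.37 and 0.57, and outside in group 2 as well at 10 CPM, percentile 99.7; C1qb rose by 1.1, SE 0.36). Cdkn1a, a p53 target, was higher in group 2 (1.09) and level in group 3 (-0.01).

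Within the central 95% in both sorted groups were the lineage lists. CD4 genes had medians of -0.03 and 0.02 with Cd4 itself at -0.19 and -0.21, and CD8 genes -0.07 and -0.16 with Cd8a at -0.09 and -0.36. Pro-survival BCL2 genes stood at 0.08 and 0.15 (Bcl2 at -0.08 and 0.06), proteasome subunits at 0.13 and 0.00, NF-kB targets at 0.02 and -0.02 (Tnfaip3 rose by 0.67, SE 0.14) and STAT and SOCS genes at 0.21 and 0.10 (Socs3 rose by 1.06, SE 0.29). NKT and innate-like genes stood at 0.36 and -0.13, Wnt targets at 0.25 and -0.15, thymic epithelium markers at -0.24 and 0.15, and stroma and endothelium markers at 0.31 and -0.16.

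**Figure D3:**
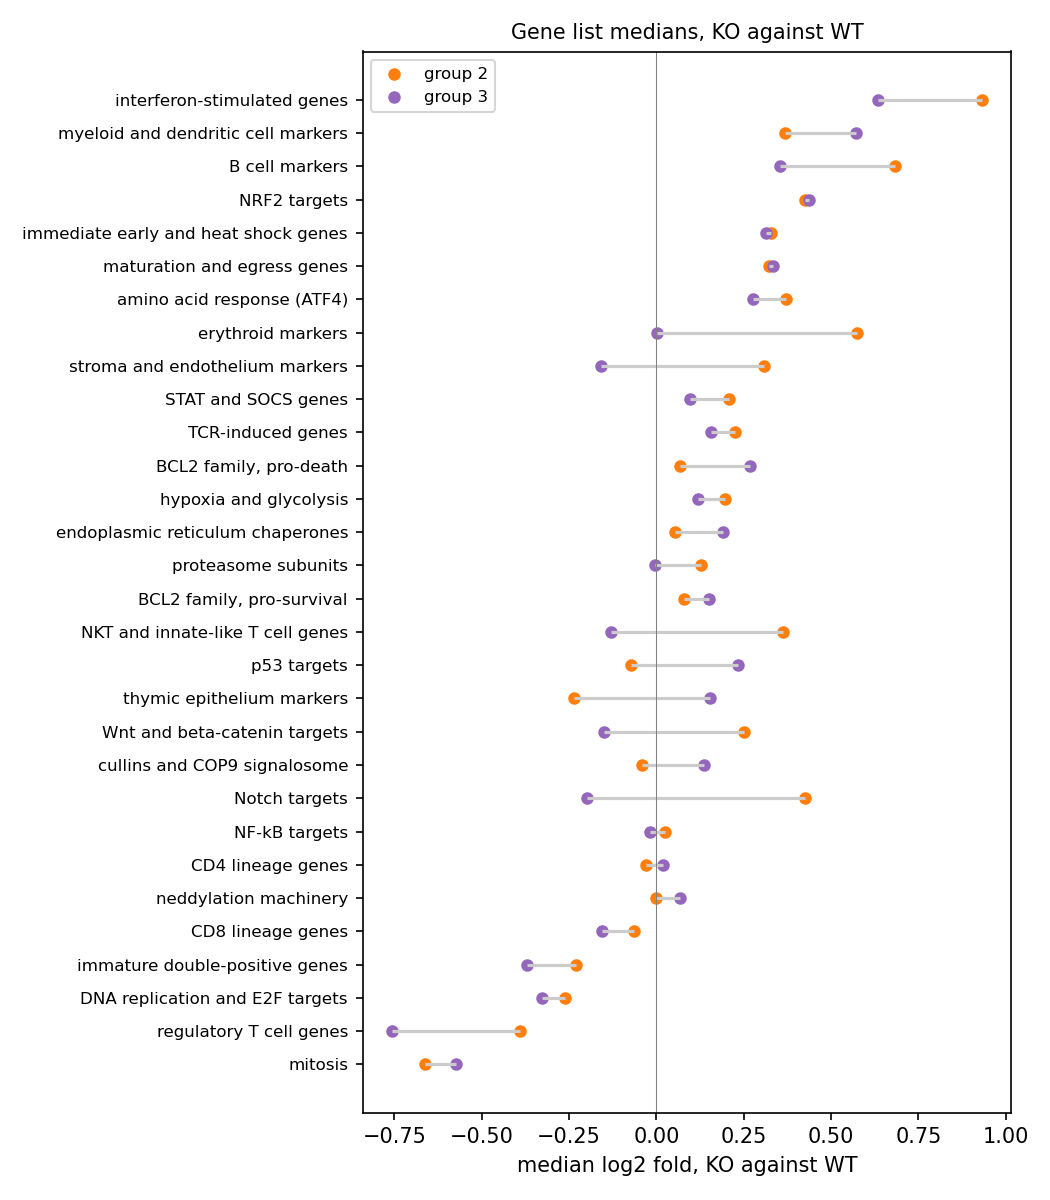
Median log2 fold of libraries labelled KO over WT (x axis) for each gene list (y axis) except sex-linked genes, in group 2 (orange) and group 3 (purple). Interferon-stimulated genes lie at 0.93 and 0.64, NRF2 targets at 0.43 and 0.44, and mitosis genes at -0.66 and -0.57.

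Across genes, the genotype folds of the sorted groups, which share no library, went together weakly over all measured genes and more among abundant ones. Nqo1, Oas1a and Ly6c1 lay on one side and Ctse, Slc45a3 and Arl5c on the other in both. Pearson's r across the 12490 genes was 0.118 and Spearman's rho 0.152, and with 10 CPM they were 0.398 and 0.315. Genes are not independent replicates. The libraries of a genotype may also come from the same mice, so agreement of the folds can reflect the mice as well as the genotype. Past 2-fold, 84 genes were higher in both sorted groups where 17.5 would be if the groups were independent, 66 were lower in both where 17.1 would be, and 164 went opposite ways where 51.7 would be. With 10 CPM the numbers were 44, 24 and 6, where 2.17, 1.06 and 3.09 would be. Opposite genes exceeded independence in both settings, so an excess over it alone does not show agreement. Most genes past 2-fold in both sorted groups went the same way with 10 CPM, but not over all measured genes.

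The step from group 2 to group 3 was compared within each genotype. Ccr7 was 3.03-fold higher in group 3 in WT (2.88 to 3.19) and 3.74-fold in the libraries labelled KO (3.53 to 3.97), and Gimap4 3.05-fold (2.88 to 3.23) and 3.87-fold (3.65 to 4.10). Acvrl1 was 6.34-fold and 3.88-fold higher, Zbtb7b 4.23-fold and 2.99-fold, and Tnfsf11 2.98-fold and 3.15-fold. Cldn10 stood at 0.122 and 0.260 of its group 2 level, Tigit at 0.162 and 0.225, and Ikzf2 at 0.371 and 0.370. In WT 652 genes were higher and 232 lower in group 3, and in the libraries labelled KO 231 were higher and 748 lower. With 10 CPM the numbers were 134 and 53, and 107 and 92. Past 2-fold, 60 were higher in both where 12.1 would be if the genotypes were independent, 46 lower in both where 13.9 would be, and 171 opposite where 43.3 would be. Among genes with 10 CPM these overlaps were 37, 16 and 7, where 1.58, 0.54 and 1.98 would be. Most of the opposite genes were thus low in counts. Opposite genes exceeded independence in both settings, so an excess over it alone does not show agreement between the genotypes. Pearson's r of the step's folds between the genotypes was 0.0081 and Spearman's rho 0.059 over the 12490 genes. With 10 CPM they were 0.295 and 0.217.

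Over both genotypes edgeR called 271 genes higher and 142 lower in group 3 (adjusted p under 0.05), and DESeq2 100 and 39; 376 of the 413 had the same direction with an interval excluding 1 in each genotype. With edgeR's own filter the numbers were 150 and 50, with no filter 0 and 0, without genotype in the model 13 and 9, and with 1 library left out 2 to 36 and 5 to 10. Ccr7 rose by 1.75 (log2, SE 0.14; edgeR, adjusted p 3.44e-31), Gimap4 by 1.78 (SE 0.14), Acvrl1 by 2.29 (SE 0.23), Adgrg3 by 1.98 (SE 0.37), Gimap3 by 1.67 (SE 0.16) and Tnfsf11 by 1.62 (SE 0.22). Zbtb7b (1.82, SE 0.31), Samhd1 (1.51, SE 0.17), Tesc (1.65, SE 0.20) and Itgb3 (1.56, SE 0.27) rose too. Tigit (-2.30, SE 0.40), Cldn10 (-2.41, SE 0.25), Jchain (-1.94, SE 0.23), Ikzf2 (-1.43, SE 0.15) and Ly6c2 (-1.43, SE 0.26) fell, as did Hivep3 (-1.10, SE 0.15), Hexim1 (-1.23, SE 0.23) and Ppm1e (-1.29, SE 0.36), while Pou2af1 did not pass. Jchain is a transcript of immunoglobulin-producing cells. Igkc fell with it (2304 and 504 counts in WT, 4328 and 595 labelled KO), so its fall need not be one of thymocytes. Bcl2 rose by 0.66 (SE 0.14) and Rag1 fell by 0.45 (SE 0.14), Rag1 and Ppm1e missed 0.05 with DESeq2, and Cd69, the sorting marker of both groups, stood at -0.28 in WT and 0.10 in the libraries labelled KO. Maturation and egress genes had medians of 0.57 and 0.56 and immature double-positive genes of -0.23 and -0.25 in the 2 genotypes, the order of the sorted groups given by the sample titles. Interferon-stimulated genes had medians of 0.83 and 0.48, with 11 of 26 called higher in group 3 (16 adjusted over the list alone). Regulatory T cell genes had medians of 0.61 and 0.41, with 4 of 13 called higher and 1, Ikzf2, lower (7 and 1 adjusted over the list alone).

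The difference of the genotype effect between the sorted groups was given by size, since 4 libraries leave no error for it. Rrp1 (3.62 in group 3 against 0.45 in group 2), Exosc5 (2.67 against -0.26), Hsp90aa1 (2.65 against 0.00), Rrp36 (2.41 against -0.24) and Lars2 (2.27 against 0.39) had the largest differences toward group 3 among genes with 10 CPM in at least 2 libraries, predicted genes left out. Atoh1 (-2.79 against 0.28), Cep112it (-2.05 against 0.94), Zfp488 (-1.04 against 1.42), Dbhos (-1.23 against 0.96) and Olfr613 (-1.17 against 1.01) had the largest the other way under the same limit, all at 20 to 368 counts per library. Below that limit, Ngp (4.15 against 0.07) and Rrp8 (2.91 against -0.26) differed by more than Exosc5. Rrp1 had 351, 426 and 404 counts in WT group 2, WT group 3 and the group 2 library labelled KO, and 6169 in the group 3 library labelled KO.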

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

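The tests of ribosome biogenesis genes in general and of strain segments were chosen after the result was seen. Cep112it, Zfp488, Dbhos and Olfr613 stand out because the library labelled KO was above WT in group 2 and below it in group 3. The genotype fold in group 3 minus that in group 2 was -2.99 for Cep112it, -2.46 for Zfp488, -2.19 for Dbhos and -2.18 for Olfr613 (log2). With 1 library per group these differences were not tested.

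All 4 genes follow a wider pattern: more genes had a count in WT group 3 (23325) and in the group 2 library labelled KO (23925) than in WT group 2 (20440) and in the group 3 library labelled KO (20521). Depth argues the other way, and with each library thinned to 8043077 counts the smaller of the first pair still had 3280 genes more than the larger of the other. Counts over 1571 receptor and keratin-associated genes that thymocytes do not use (Olfr, Vmn, Tas, Krtap and Mup symbols) summed to 181 and 214 CPM in those libraries against 87.9 and 98.5 CPM, a ratio of 1.84 or more, so reads from genomic DNA or other background may explain part of the balance of low genes in each comparison. Ribosomal protein genes went opposite, with median log2 folds of -0.12 in group 2 and 0.23 in group 3. A genotype effect that differs between the sorted groups stays open and was not tested.

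The 8 measured genes with Rrp symbols, a set chosen after its values were seen, were all at least 2-fold higher in the group 3 library labelled KO than in WT (median log2 fold 2.58, range 1.66 to 3.62), and 2 of them, Rrp12 and Rrp7a, also in group 2 (1.72 and 1.1). Of the 8, 0 share a 31-base stretch with transcripts of Gm42418 or Gm26917, which overlap ribosomal RNA and were themselves 15.8-fold and 6.69-fold higher. Only exact matches to the transcripts of these genes were sought, so ribosomal RNA reads counted in the Rrp genes stay open. Reads shared between the Rrp genes are argued against: 0 of the 8 share an exact 31-base stretch with another. A rise of ribosome biogenesis genes in general would need a median near that of the Rrp genes, and 39 other such genes had a median of 0.13 in group 3, with Exosc5 the 1 past 2-fold; Dis3, an exosome subunit outside that set of symbols, was 4.02-fold higher (58 and 272 counts). A fault of this library that was not tested, or an effect of the genotype in group 3 alone, may be the source.

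Genes past 2-fold in the same direction in both sorted groups lay close together on chromosomes. Of 149 such genes with a position, 52 had another within 1 Mb, against a mean of 32.0 in random sets of measured genes. Of 10000 random sets, 27 had as many. Ctse with Slc45a3 (chromosome 1), Dtx1 with Oas1a (chromosome 5) and Ly6a with Ly6c1 (chromosome 15) went the same way. Other neighbours went opposite ways, among them lower Ptprv with higher Lad1 (chromosome 1), Wdr35 with Sdc1 (chromosome 12) and Ptcra with Vegfa (chromosome 17). Neighbours of one family do not account for the closeness, as 48 remained once pairs with a shared symbol stem were left out. Of 10000 random sets, 76 reached that number. The flank of Uba3 is argued against, with 0 of the 52 within 10 Mb of it. Segments of another strain background that differ between the mice may be a source: the 105 genes past 2-fold in the same direction in both sorted group comparisons had 22 with a neighbour, against a mean of 16.8, an excess of 1.31 where the genotype genes had 1.63, while neighbours regulated together by the genotype stay open.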

How the results depend on the processing

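Leaving out each library was chosen after seeing the data, as were robust shrinkage, genes with the same direction in both pairs and lists without shared members. No list median or single gene fold past its threshold changed direction except the group 3 median of pro-death BCL2 genes. That median went from 0.27 to -0.01 without shared members. Of 117 values for the comparisons 51 kept their side or size, 297 of 306 list medians did, and 972 of 1002 single folds did. Numbers of genes past 2-fold followed the filter and the rule by construction. Higher and lower, in the order group 2 genotype, group 3 genotype, WT step, KO step, they were 2419 and 551, 443 and 1816, 1799 and 483, and 427 and 1951 with no filter beyond 1 count; 176 and 103, 112 and 94, 134 and 53, and 107 and 92 at 10 CPM; 314 and 112, 124 and 180, 203 and 86, and 121 and 220 with a pseudocount of 2 CPM; and 292 and 73, 85 and 196, 177 and 55, and 61 and 250 with the 3-fold rule. The share that was higher among group 3 genotype genes passed from 27.9% to 54.4% at 10 CPM, and that of the KO step from 23.6% to 53.8%. In both, the balance of higher and lower genes thus reversed.

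For the shared genotype effect, genes higher and lower by edgeR were 0 and 1 with no filter (1312 at an unadjusted p under 0.05), 179 and 84 with filterByExpr, 28 and 11 without sorted group in the model, and 125 and 54 with DESeq2. For the shared sorted group effect they were 0 and 0 with no filter (1030 at an unadjusted p under 0.05; DESeq2 under the usual filter called 139), 150 and 50, 13 and 9 without genotype in the model, and 100 and 39. Leaving out 1 library forces a model without the other factor, in which the lone library is assumed to vary like the others: genotype genes were then 25 to 80 higher and 11 to 42 lower, and sorted group genes 2 to 36 higher and 5 to 10 lower. The lowest came without WT group 2, except for sorted group genes lower, where it came without KO group 3; beyond the change of model or filter, the cause was not tested. limma-voom called 500 genotype genes, 486 of them among the 593, and robust shrinkage 584, of which 552 were shared. Pearson's r of the genotype folds moved from 0.118 to 0.398 at 10 CPM and to 0.222 with a pseudocount of 2 CPM, both of which reduce the weight of low genes. Depth limits genes under about 2 CPM, where 1 library decides whether a fold can be given.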

Other observations

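A hypothesis chosen from the list medians was tested: that the libraries labelled KO hold a larger share of mature cells, which may raise maturation and interferon genes in both. Genes that rose from group 2 to group 3 in both genotypes, 254 of them, had a median genotype log2 fold of 0.27 over both sorted groups, 0.25 without the interferon list, and 79.5% of them were above 0. The 122 that fell had a median of -0.10, at the edge of the bound set for it. Over all measured genes the medians were 0.00 in group 2 and -0.01 in group 3, but the share above 0 was not taken for them. Maturation genes, from which the hypothesis also came, were not left out of the 254. Ccr7 (log2 folds -0.29 and 0.02) and Il7r (-0.66 and -0.29) did not go with the hypothesis. Nor did the regulatory T cell list. It rose from group 2 to group 3 (medians 0.61 in WT and 0.41 labelled KO). By genotype it was lower (-0.39 in group 2 and -0.76 in group 3). NF-kB targets rose with the step (0.26 and 0.22) and were level by genotype (0.02 and -0.02). The immediate early list rose in both comparisons, and the mitosis and immature double-positive lists fell in both. A direct effect of the genotype on maturation and interferon genes stays open.

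Some transcripts of neutrophils and of immunoglobulin-producing cells differed sharply between libraries. Ltf had 72 counts in the group 3 library labelled KO and at most 1 elsewhere, S100a9 62 counts against 0 in WT group 3 (at least 17.7-fold higher against a floor of 3 counts, 14.0-fold at the lower limit of the interval) and 9 in WT group 2, and S100a8 38 against 0 in WT group 3 (at least 10.8-fold higher, 8.4-fold at that limit), beside Ngp with 204. Ighg1 had 1400 counts in the group 2 library labelled KO and 2, 1 and 2 in WT group 2, WT group 3 and the group 3 library labelled KO. Ighg2b had 655, 16, 348 and 21 counts and Ighg2c 620, 5, 881 and 23 in WT group 2, WT group 3, and the group 2 and group 3 libraries labelled KO. Igkc had 2304, 504, 4328 and 595 counts in that order, and Jchain 359, 100, 505 and 108. These genes were chosen after their values were seen.

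BC018473 (chromosome 11, 116752167 to 116759373) had 2702 and 1918 counts in WT groups 2 and 3 and 9 and 10 in the libraries labelled KO, and Gm8822 on chromosome X had 376 and 258 against 1 and 5. Both were picked after their values were seen; the naming rule leaves out such symbols.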
